A study of Enchytraeus crypticus with 9 samples.

How the data were processed

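The series measured gene expression in embryos of Enchytraeus crypticus, a small white oligochaete worm (potworm) that lives in soil and is used in soil toxicity testing. The worms lay their eggs in cocoons, in which the embryos develop. Whole cocoons were exposed for 1 day to LUFA 2.2 soil, a natural standard soil, that held no added cadmium, 5 mg Cd/kg or 16 mg Cd/kg. Each of the 9 samples was a pool of 300 cocoons, and each group had 3 samples. The labels call the 3 samples of a group biological replicates, so p-values measure the spread between pools of cocoons.

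Total RNA was amplified, labelled with the green dye Cy3 and hybridised to a 1-colour Agilent array, together with spike-in RNA of known makeup, per the labels' protocols. The deposited intensity values are the processed signals of Agilent Feature Extraction 10.7.3.1, per the file headers, which are each array's own background-subtracted brightness on a linear scale with no scaling between arrays. The deposited flag columns of the same files, per the file headers, mark each spot as well above background, non-uniform, a population outlier or saturated. The series table holds the authors' intensity values of the same arrays. Set against the scanner values by feature number, these differed by at most 0.497%, so they are the processed signals rounded, on the same linear scale and with no centring. The medians of its columns were 15.6, 15.0 and 13.6 for control arrays 1 to 3, 7.23, 7.41 and 11.3 for the 5 mg arrays, and 7.99, 12.0 and 13.8 for the 16 mg arrays.

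The array carried 43750 probes, 1 spot each, and 1417 control features, which were left out of every test. All 43750 probes have an identifier of their own: 23177 are named as contigs (assembled sequences) and 20573 carry names in the form of single sequencing reads. The files do not pair these identifiers with gene names, so the 23 gene lists fixed at the start were not tested, and at most 2 probes that rose and 2 that fell are named per comparison. No spot was saturated, and 63 spots marked as non-uniform or outlying were left out.

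Levels were log2 of the processed signal minus the 75th percentile of the array, so that a level of 0 is the brightness of the 75th percentile. Tested probes were the 25915 that were well above background on all 3 arrays of at least 1 group. The test was limma (3.58.1, in R 4.3.3; tables read with data.table, version 1.17.8), with lmFit and eBayes on all 9 arrays in 3 groups, two-sided, and with Benjamini-Hochberg adjustment over the tested probes at a threshold of 0.05. This fit had 6 residual degrees of freedom and 4.49 prior degrees of freedom. A moderated F test asked for any difference between the 3 groups. Every comparison was also fitted with only the 2 groups compared. The design, the tests, the rule for naming probes and a first set of alternatives were chosen before the data were examined.

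Named probes were, in each direction of a comparison, the 2 past the threshold with the largest absolute log2 fold change, or, where none passed, the 2 with the smallest unadjusted p. Where a probe was not well above background on any array of a group, its fold is given as a lower bound. That bound sets the mean of the brighter group against the dim group's mean of, per array, the higher of the probe's own level and the lowest level of any probe well above background.

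The fit was tested on simulated data made from 25869 probes with the spread of each group. For 5 mg Cd/kg against control, it recovered 7.81% of probes changed by 1 on the log2 scale, 55.1% of those changed by 2 and 83.6% of those changed by 4, with 81 false calls. The fit of those 2 groups alone recovered 0%, 39.1% and 71.6%, with 21 false calls. For 16 mg Cd/kg against control, the fit over 9 arrays recovered 1.49%, 38.5% and 79.4%, with 2 false calls, and the fit of 2 groups recovered 11.9%, 61.5% and 91.2%, with 12 false calls. Of the calls at 5 mg, 45% were false in the fit over 9 arrays and 21.9% in the fit of 2 groups, and at 16 mg 2.44% and 9.84%, with 200 changed probes in each case, and between the doses 57% and 8.16%. In these simulations, with 1 draw per comparison, the false share lay above the threshold of 0.05 in the fit over 9 arrays at 5 mg and between the doses, and in the fits of 2 groups. Between the doses the fit of 2 groups made 45 true and 4 false calls, too few to show an excess. These simulations take the SD of 3 arrays as the true spread of a probe.

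Per the file headers, the 9 arrays lay on 3 slides and were scanned in 5 sessions. Sessions 3 and 4 held 1 control array each, session 1 held control array 3 with 5 mg array 2 and 16 mg array 1, and sessions 2 and 5 held only cadmium arrays. Slide 1 held control arrays 1 and 3, 5 mg array 2 and 16 mg array 1. Slide 2 held control array 2, 5 mg array 3 and 16 mg arrays 2 and 3. The first array of the 5 mg group was alone on slide 3 and in its own scan session. A block for slide thus takes up that array, and a fixed block for scan session takes up that array and control arrays 1 and 2. With the session block, every contrast with control rests on control array 3. Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, the values of the series table, other filters on dim probes, marked spots left in, eBayes with trend and robust options, array weights, only the 2 groups compared, the replicate number or the slide as a block, and each array left out in turn. The normexp alternative was planned on mean spot signals and used the median spot and background signals, which the files hold. A choice of 1 probe per gene was not run, because no gene names were used. Alternatives chosen after the data were seen were cyclic loess, scaling on the spike-ins, scan session as a random block (duplicateCorrelation, with statmod 1.5.0) or a fixed block, each of slides 1 and 2 alone, and array weights estimated per group. The spike-in scaling used the 8 of 10 E1A sequences (320 features in all) that were well above background at every feature of every array.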

Results

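Expression was compared between cocoons of E. crypticus kept for 1 day in clean soil or in soil with 5 or 16 mg Cd/kg, concentrations that the series describes as known to affect embryonic development. Cadmium is a toxic metal. Each group had 3 arrays, each from a pool of 300 cocoons. Probes well above background numbered 28727, 29481 and 26173 on the control arrays, 19614, 20604 and 23287 on the 5 mg arrays, and 22361, 27239 and 26346 on the 16 mg arrays. The means were 28127 ± 1734 (SD, n = 3) in controls, 21168 ± 1900 (SD, n = 3) at 5 mg Cd/kg and 25315 ± 2597 (SD, n = 3) at 16 mg Cd/kg. Every 5 mg array had fewer such probes than every control array (exact permutation test, two-sided, p = 0.1, the smallest value that 3 against 3 allows). The difference at 16 mg Cd/kg was within the spread of the arrays (exact permutation test, two-sided, p = 0.3). The 75th percentile of the processed signal, which the count of probes above background can follow, was 78.1, 74.4 and 74.5 on the control arrays, 38.3, 50.5 and 84.9 at 5 mg, and 48.9, 79.6 and 87.3 at 16 mg Cd/kg. The mean local background was 29.9, 31.2 and 35.2, then 43.8, 38.4 and 35.3, then 38.6, 37.4 and 34.8, so the loss of probes was not separated from the brightness and background of the arrays. The number of arrays limits the precision of every value below.

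**Figure D1:**
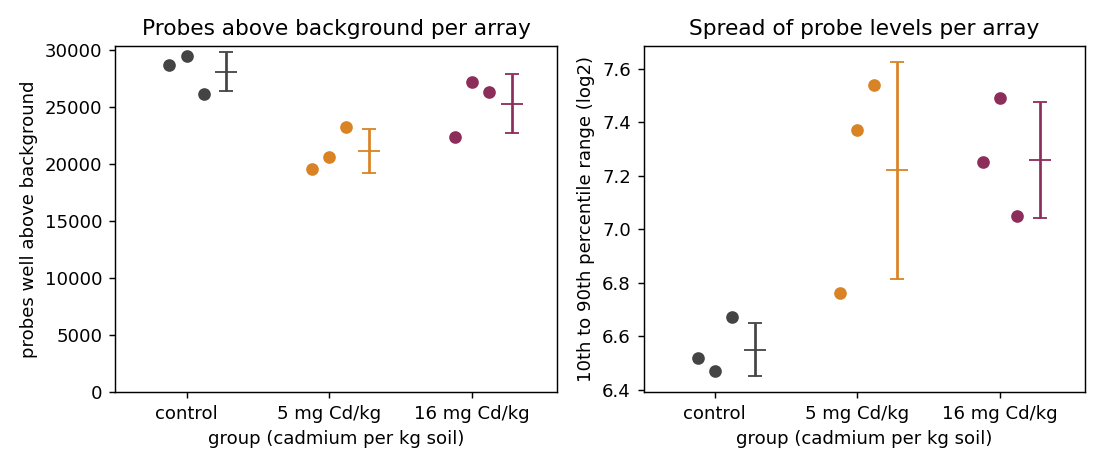
Left, the number of probes well above background on each array (points), with the group mean and SD (bars) beside them. Right, the range between the 10th and 90th percentile of log2 levels of the 16952 probes above background on all 9 arrays; the controls sit at 6.55 ± 0.10 (SD, n = 3), below all 6 cadmium arrays.

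Of the 43750 probes on the array, 2632 were above background on all 3 control arrays and on no 5 mg array, and 14 showed the opposite. At 16 mg Cd/kg the counts were 676 and 35. Both doses shared 588 probes that were above background in all controls and on no cadmium array, and 4 that were above background on all 6 cadmium arrays and no control. Between the doses, 367 probes were above background on all 3 arrays at 16 mg Cd/kg and on none at 5 mg Cd/kg, against 3 the other way. Without control array 3, the count lost at 16 mg Cd/kg was 1322, and without 16 mg array 2 or 3 it was 1109 or 1325. Leaving out an array can only keep or raise this count, since fewer arrays have to meet the rule.

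The spread between arrays differed between groups. The median SD of a tested probe was 0.20 on the log2 scale in controls, 0.69 at 5 mg Cd/kg and 0.38 at 16 mg Cd/kg, and 91% of probes at 5 mg and 78% at 16 mg had a larger SD than in controls. Across probes, control arrays correlated with each other at r = 0.987 to 0.989, 16 mg arrays at 0.970 to 0.974 and 5 mg arrays at 0.860 to 0.949. The first 5 mg array, alone on its slide, correlated with the 8 others at 0.857 to 0.900. All other pairs lay at 0.914 to 0.989. Among these, 5 mg arrays 2 and 3 correlated at 0.949 with each other and at 0.947 to 0.977 with the 16 mg arrays.

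The first comparison asked which transcripts differed after 1 day at 5 mg Cd/kg. Of 25915 tested probes, 3756 (14.5%) passed the threshold in limma, 2317 higher and 1439 lower than in controls. In simulated data with 200 changed probes, 45% of the calls of this fit at 5 mg Cd/kg were false, and 21.9% in the fit of 2 groups. These shares depend on the number of changed probes, so they do not give the false share of the 3756. The higher probes had a median log2 fold change of 1.49 and the lower ones fell by 1.60. More than 4-fold changes were fitted for 331 higher and 294 lower probes. For 3753 of the 3756 called probes, all 3 cadmium arrays lay on the same side of all 3 controls. Over all tested probes, 5694 lay above and 5383 below every control in this way (42.7%, where chance gives 10% for groups of equal spread). It was 65.2% without 5 mg array 1, 60.4% without 5 mg array 2 and 46.3% to 47.1% without each other array, where chance gives 20% for groups of equal spread. The controls varied less (median SD 0.20 against 0.69), so unchanged probes separate more often than 10% or 20%. By how much was not simulated for this comparison. The median of all tested probes was -0.25 on the log2 scale, a sign that turned with the filter on dim probes, to 0.21 among probes above background on all 9 arrays and 0.17 with no filter.

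Among the probes with the largest changes, contig16069 was not well above background on any control array and was above it on all 3 arrays at 5 mg Cd/kg, where it was at least 6.22-fold higher (limma adjusted p = 0.0266). This bound holds for the scale of the 75th percentile: with normexp (offset 50) and quantile the log2 fold change was 0.38, in a range of 0.38 to 5.04 over the alternatives. GYUW2K401A4PTR went from a level of -3.56 ± 0.56 (SD, n = 3; above background on 2 control arrays) to 0.40 ± 0.22 (SD, n = 3), a log2 fold change of 3.95 with an SE of 0.65 (limma adjusted p = 0.0266). Over 26 alternatives it ranged from 1.03 (normexp and quantile) to 4.31, with adjusted p from 0.000627 to 0.127, and 8 lost the call. Among bright probes, contig02266 fell by 5.14 on the log2 scale (SE 0.71), from 5.35 ± 0.15 to 0.20 ± 0.38 (SD, n = 3 each; limma adjusted p = 0.0266), and both slides that held controls showed it, at -4.81 and -5.11. GYUW2K402HLWR3 fell by 5.16 (SE 1.41; limma adjusted p = 0.0403), but its level at 5 mg Cd/kg was -0.14 ± 3.70 (SD, n = 3), since array 2 kept a level of 4.10, beside controls at 4.11 to 5.91. With only the 2 groups compared its adjusted p was 0.0831, in a range of 0.000558 to 0.477 over the alternatives. The files do not pair these identifiers with gene names.

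**Figure D2:**
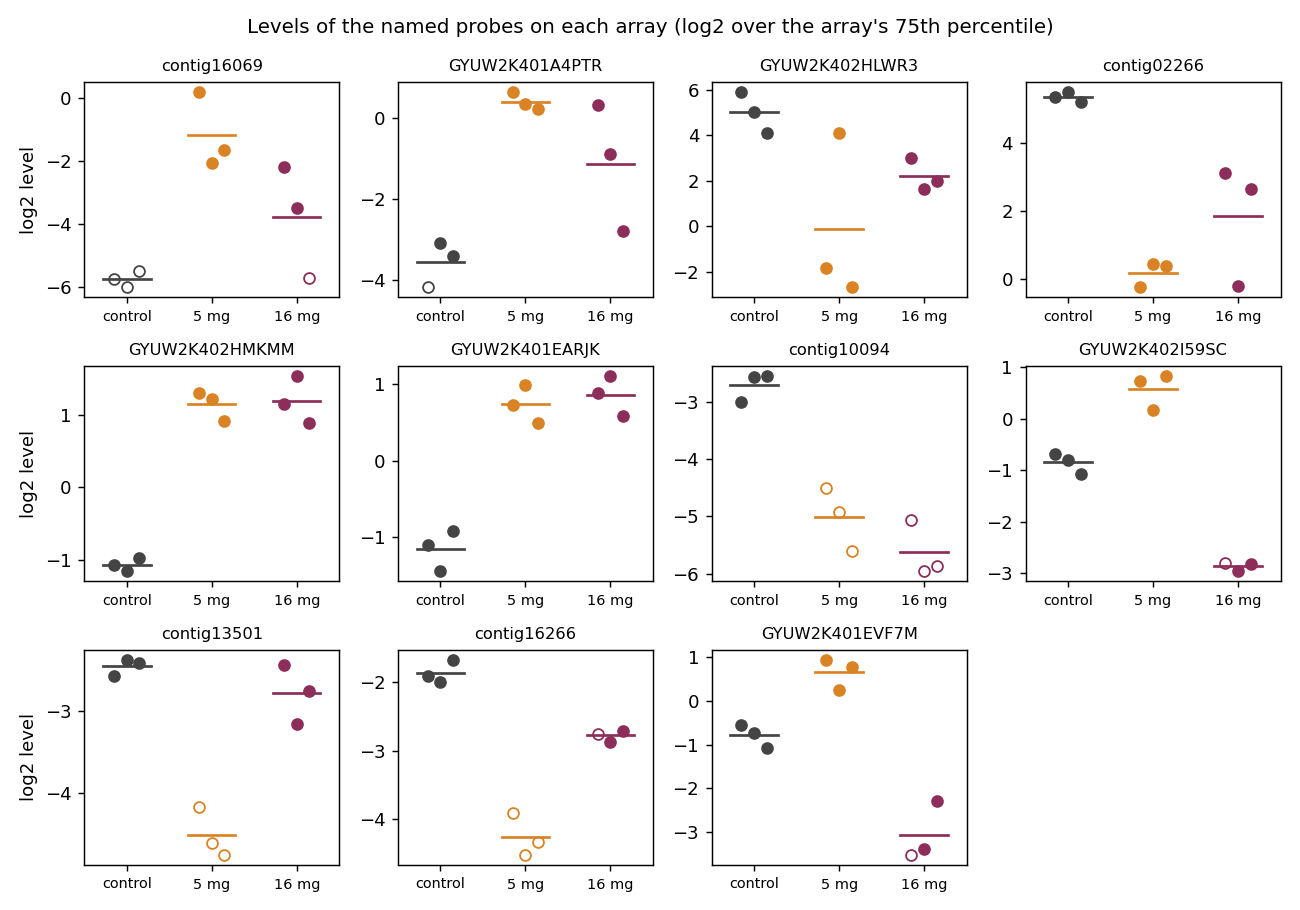
Levels of the 11 named probes on each array, as log2 over the 75th percentile of the array, in control, 5 mg and 16 mg Cd/kg groups; filled points are well above background, open points are not, and lines are group means. For contig02266 the 3 controls lie at 5.19 to 5.49 and all 6 cadmium arrays lie lower.

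The number of called probes at 5 mg Cd/kg rested on how the spread was estimated and on single arrays. Fitting only the 2 groups called 1209 (807 higher and 402 lower), of which 1179 were among the 3756. Leaving out any control array or 5 mg array 3 took that fit of 2 groups to 0, and leaving out 5 mg array 1 or 2 to 9602 or 6369. In the fit over all arrays, array weights called 16197, the slide as a block 8403, and weights per group or no filter on dim probes 0. Leaving out control array 1, 2 or 3 or 5 mg array 3 left 0, 5 mg array 1 or 2 left 9206 or 8114, and 16 mg array 1 left 1619. The scan session as a fixed block also left 0, but its contrasts with control rest on control array 3 alone. That 0 thus does not show that session made the calls. Within slides 1 and 2, which hold the same arrays that selected the probes, 2316 of the 2317 higher and 1438 of the 1439 lower probes kept their direction on both, with medians of 1.27 and 1.42 and of -1.62 and -1.79. Scaled on the spike-ins, 2531 probes passed with 197 higher and 2334 lower (7.78% higher, against 61.7%), and the median of all probes fell by 0.62 instead of 0.25, so directions are relative to the 75th percentile of each array. The balance also turned without a change of scale: 3519 were higher and 5687 lower (38.2% higher) without 5 mg array 1, 6745 and 9452 (41.6%) with array weights, and 3034 and 5369 (36.1%) with the slide as a block, against 4931 and 3183 (60.8%) without 5 mg array 2. The first 3 of these settings are not separate checks, since each removes or weighs down 5 mg array 1. The slide block takes up that array, and the array weights of 5 mg arrays 1 to 3 were 0.115, 0.229 and 1.8.

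The second comparison asked the same of 16 mg Cd/kg. The fit over all 9 arrays called 0 probes in limma, with a smallest adjusted p of 0.112, while 7274 probes (28.1%) had an unadjusted p under 0.05, where chance gives 5%. Fitted with the 16 mg and control arrays alone, limma called 11035 probes, 5231 higher and 5804 lower, with a smallest adjusted p of 0.0133. All 3 cadmium arrays lay above every control for 7270 tested probes and below every control for 7888, together 58.5% where chance gives 10% for groups of equal spread. The controls varied less here too (median SD 0.20 against 0.38), so chance gives more than 10%, by an amount that was not simulated. The fitted change was above 2-fold for 2769 higher and 3634 lower probes. The median of all tested probes was -0.07 on the log2 scale, against 0.27 among probes above background on all 9 arrays, 0.07 with no filter, 0.06 with the scan session as a block and -0.23 with spike-in scaling.

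The probes with the smallest p at 16 mg Cd/kg did not pass the threshold in the fit over all arrays. GYUW2K402HMKMM had a level of -1.06 ± 0.09 in controls and 1.19 ± 0.33 at 16 mg Cd/kg (SD, n = 3 each), a log2 fold change of 2.25 with an SE of 0.30 (limma adjusted p = 0.112). GYUW2K401EARJK stood at -1.16 ± 0.27 and 0.86 ± 0.26 (SD, n = 3 each), a log2 fold change of 2.02 (limma adjusted p = 0.112). Probe contig10094 was above background on all 3 control arrays and on no array at 16 mg Cd/kg, with a level at least 1.77-fold higher in controls on the scale of the 75th percentile (limma adjusted p = 0.112), while with normexp and quantile its log2 fold change was -0.18. GYUW2K402I59SC had a log2 fold change of -2.01 with an SE of 0.31 (limma adjusted p = 0.112). With the 2 groups alone, each of the 4 had an adjusted p of 0.0133, and over the alternatives the values ranged from 0.00207 to 0.521, 0.00277 to 0.524, 0.00207 to 0.521 and 0.00229 to 0.521 in this order. GYUW2K402HMKMM and GYUW2K401EARJK had levels of 1.14 ± 0.20 and 0.74 ± 0.25 (SD, n = 3 each) at 5 mg Cd/kg.

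The pooled spread of the fit over all arrays includes the 5 mg arrays. At 16 mg Cd/kg this fit called 4657 probes without 5 mg array 1, 0 without 5 mg array 2 and 0 without 5 mg array 3. It called 11098 with array weights and 8 with the slide as a block, settings that also change other parts of the model. The fit of 2 groups called 0 without control array 1 or 3 and 1883 without control array 2, against 6585 to 12598 without each of the 16 mg arrays.

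The third comparison set the doses against each other. At 16 mg Cd/kg, 27 probes were lower than at 5 mg Cd/kg and 0 were higher (limma, 1426 probes or 5.5% with an unadjusted p under 0.05, where chance gives 5%; 0 called with the 2 groups alone, smallest adjusted p 0.312). All 3 arrays at 16 mg lay above every 5 mg array for 718 tested probes and below for 1146, together 7.19% where chance gives 10% for groups of equal spread. But this rested on single arrays: it was 25.6% without 5 mg array 2 and 11.7% to 19.9% without each other cadmium array, where chance gives 20% for such groups. In 20 simulated draws with no change, the fit over all arrays called 1 to 76 probes (median 36) with the spread of each group, and 0 in every draw with a pooled spread. In these draws 11.4% of probes had an unadjusted p under 0.05 with the spread of each group, and 5.14% with a pooled spread. The doses were fully separated for 13.3% and 9.93% of probes. The observed 5.5% and 7.19% thus lay below the values simulated with the spread of each group. All 27 were fitted higher than control at 5 mg Cd/kg, with a median log2 fold change of 1.43, and below control at 16 mg Cd/kg, with a median of -1.13. The median difference was -2.55. A selection on this difference favours controls between the doses: among the 27 lowest probes by p in the simulated draws, 67.2% lay above control at 5 mg and below it at 16 mg with the spread of each group, and 85.4% with a pooled spread. For 26 of the 27, every 5 mg array lay above and every 16 mg array below all 3 controls, and 26 also passed the threshold against control at 5 mg Cd/kg, against 0 at 16 mg Cd/kg. They comprised 11 contigs and 16 read-named probes, all above background on every control and every 5 mg array. In the simulated lists of 27, such separation around the controls held for 23% with the spread of each group and 20.2% with a pooled spread. The draws vary each probe independently, so they give no range for probes that move together.

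GYUW2K401EVF7M fell by 3.73 on the log2 scale between the doses (SE 0.39, limma adjusted p = 0.0236), from 0.66 ± 0.36 to -3.07 ± 0.68, with controls at -0.79 ± 0.26 (SD, n = 3 each). GYUW2K402I59SC fell by 3.43 (SE 0.31, limma adjusted p = 0.00966), from 0.58 ± 0.36 to -2.86 ± 0.10, with controls at -0.85 ± 0.20 (SD, n = 3 each). Over the alternatives the 2 differences ranged from -4.12 to -1.02 and from -3.72 to -1, both smallest with normexp and quantile, and 11 of 26 lost the call for each. Both were above background on 2 of the 3 arrays at 16 mg Cd/kg. The probes nearest to passing in the other direction, contig13501 and contig16266, were not well above background on any 5 mg array and had limma adjusted p-values of 0.0783 and 0.107. The count of 27 became 7 with the slide as a block, 0 with the scan session as a block, 0 with spike-in scaling, 0 without control array 1 or 2 or 16 mg array 1 or 2, and 1 without control array 3 or 16 mg array 3. Both blocks take up 5 mg array 1, so their counts rest on the other cadmium arrays. Probes higher at 16 mg also passed in some settings: 13 beside 70 lower with array weights, and 3 beside 27 lower without 5 mg array 2. All 27 were lower within slide 1 and within slide 2, with medians of -2.45 and -2.25, on the arrays that selected them.

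The moderated F test for any difference between the 3 groups called 1 probe, GYUW2K402I59SC (limma adjusted p = 0.037), with 8133 at an unadjusted p under 0.05. Without 5 mg array 1, 2 or 16 mg array 3 it called 7274, 5627 or 737 probes, and without any control array, 5 mg array 3 or 16 mg array 1 it called 0. The slide as a block gave 4939 and the scan session as a block 0. With the session block only control array 3 informs the contrasts with control, so its 0 does not show an effect of session.

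The doses were then compared over all tested probes, as a correlation across probes, which are not independent replicates. The log2 fold changes against control correlated at r = 0.817 (Spearman rho = 0.823) with a covariance of 0.708 over 25915 probes. Both sets of fold changes share the 3 control arrays, and simulated groups with no effect gave r = 0.139 and a covariance of 0.028 with the spread of each group, or r = 0.501 and 0.14 with a pooled spread. The simulated probes vary independently, so they give no range for r where probes move together. The 3 controls cannot be split into sets of at least 2, so part of the excess in r may come from the shared controls. Fold changes taken within slides share no array: 5 mg on slide 1 against 16 mg on slide 2 gave r = 0.574, and 5 mg on slide 2 against 16 mg on slide 1 gave r = 0.714. The same dose on both slides gave 0.593 at 5 mg and 0.699 at 16 mg Cd/kg.

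Of the 3756 probes called at 5 mg Cd/kg, 3629 (96.6%) had the same sign at 16 mg Cd/kg. In groups simulated with no change and the same controls, the 3756 probes with the smallest p at 5 mg had the same sign in 60.6% with the spread of each group and in 83.8% with a pooled spread. Those called higher at 5 mg had a median log2 fold change of 1.00 at 16 mg, and those called lower a median of -1.21. Among the 2317 called higher, 1626 were also called higher at 16 mg Cd/kg in the fit of 2 groups, where independent lists would share 468, and 35 were called lower. Among the 1439 called lower, 1188 were called lower at 16 mg, against 322 for independent lists, and 0 were called higher. With the spread of each group, lists of these sizes from the simulated groups shared 691 higher and 456 lower probes. With a pooled spread, which gives the controls the spread of the cadmium arrays too, they shared 1263 and 926. Part of the overlap can thus come from the shared controls. Fold changes within slides, which share no array, also correlated between the doses, at r = 0.574 and 0.714. This argues against the shared controls as the whole source of the agreement between doses. Counted by position alone, 4134 probes (16%) had all 6 cadmium arrays above every control and 4073 (15.7%) had them below, where chance gives 1.19% each for groups of equal spread. The controls varied less than the cadmium arrays, so chance gives more than this, by an amount that was not simulated.

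**Figure D3:**
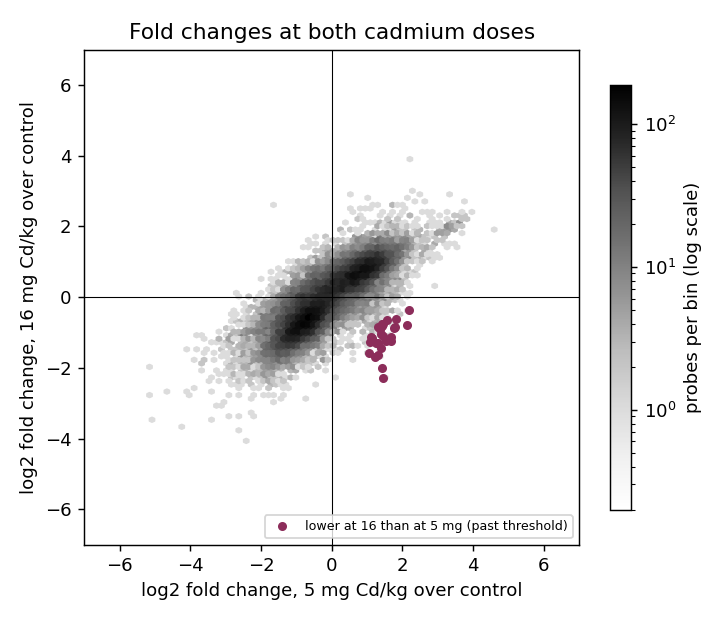
Log2 fold change over control at 5 mg Cd/kg (horizontal) and 16 mg Cd/kg (vertical) for the tested probes, with the number of probes per bin in grey on a log scale. The 27 coloured points are the probes past the threshold as lower at 16 than at 5 mg Cd/kg, and all tested probes together gave r = 0.817.

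Contig-named and read-named probes, a division made after their values were seen, moved apart. Read-named probes had a median log2 fold change of 0.00 at 5 mg and 0.23 at 16 mg Cd/kg, and contig-named probes -0.43 and -0.38, differences of 0.43 and 0.61. Of the contig-named probes called at 5 mg Cd/kg, 1059 were higher and 955 lower (52.6% higher), and of the read-named ones 1258 and 484 (72.2% higher). Per array, the difference of the class medians lay between -0.02 and 0.00 on the controls, at -0.06, 0.57 and 0.88 on the 5 mg arrays and at 0.42, 0.79 and 0.43 on the 16 mg arrays.

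**Figure D4:**
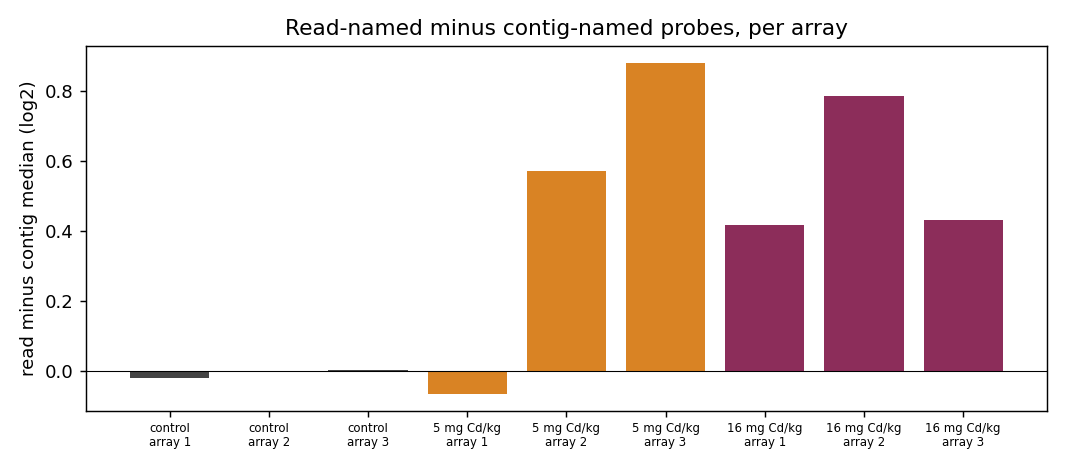
Median level of read-named probes minus that of contig-named probes on each array, after subtracting each probe's control mean (log2). Bars start at 0; 5 of the 6 cadmium arrays lie at 0.42 to 0.88, while 5 mg array 1 lies at -0.06, near the controls.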

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

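The doses differed for 27 probes in the fit over all arrays, all lower at 16 than at 5 mg Cd/kg. With array weights 70 were lower and 13 higher, and without 5 mg array 2 it was 27 and 3. The simulated draws, the slide and scan session subsets and the spike-in scaling were tests chosen after the result was seen. The largest differences were those of GYUW2K401EVF7M, at -3.73 on the log2 scale, and GYUW2K402I59SC, at -3.43. Over all tested probes, 7.19% had the arrays of both doses fully separated, where chance gives 10% and the draws with the spread of each group 13.3%. Without 5 mg array 2 it was 25.6%, where chance gives 20% for groups of equal spread. Every 5 mg array lay above and every 16 mg array below all controls for 115 probes (0.444%), and 5 (0.0193%) showed the opposite. Groups simulated with no change gave 0.428% for the first pattern with the spread of each group and 0.059% with a pooled spread. The count of 27 may come from false calls, since the pooled spread includes the tighter controls. With the spread of each group, 14 of 20 draws called as many probes, and 0 of 20 did so with a pooled spread. As many in 1 direction only were called in 0 of 20. The draws vary each probe independently, which makes such a result very unlikely by construction, so the direction does not decide. False calls thus cannot be told apart from a change between doses. The count was 0 with the 2 groups alone, where the spread is that of the cadmium arrays only. Leaving out the first 5 mg array, which was alone on its slide and in its scan session, kept a median difference of -2.4 and 22 of the 27 past the threshold. This argues only weakly against that array as the source, since the 27 were selected on every 5 mg array, which favours probes where these agree. A change of direction between doses and differences between the pools of cocoons stay open, as untested. Of the 10 splits of the 6 cadmium arrays, 1 called as many probes (27, the real one, with 0 as the highest of the others), which is too few splits for a share under 0.05.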

How the results depend on the processing

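Cyclic loess, spike-in scaling, the scan session settings, the single slides, the array weights per group and the simulated correlations were chosen after the data were seen; the other settings were planned. The correlation of the doses stayed between 0.663 and 0.89 in 26 alternatives. Simulated groups with no change, fitted with the arrays and model of 17 settings (the reported one included), gave 0.0925 to 0.745, and the observed value lay above both simulated values in all 17. The 10 other settings were not simulated. The 17 are not separate tests, since they reuse the same 9 arrays and 1 draw per kind of spread. The draws vary each probe independently, so they give no range for r where probes move together. The named probes kept their sign in all 316 alternative values, of which 230 kept their side of the threshold, 60 no longer passed and 26 newly passed. Their sizes depended on the signal scale: with normexp and quantile, whose offset of 50 compresses dim probes by construction, the log2 fold change of contig16069 went from 4.60 to 0.38, of GYUW2K401A4PTR from 3.95 to 1.03, of contig10094 from -2.92 to -0.18, of GYUW2K402I59SC at 16 mg from -2.01 to -0.34 and between doses from -3.43 to -1, of GYUW2K402HMKMM from 2.25 to 1.01, of GYUW2K401EARJK from 2.02 to 0.82 and of GYUW2K401EVF7M from -3.73 to -1.02. GYUW2K402HLWR3 ranged from -7.73 to -0.92 over all alternatives. At 5 mg Cd/kg (3756 probes), 2385 passed with normexp and quantile, 16197 with array weights, 8403 with the slide as a block, 10941 on slide 1 alone, 2 on slide 2 alone, 1209 with the 2 groups alone, and 0 with no filter on dim probes (43750 probes tested), with the scan session as a fixed block and with weights per group. At 16 mg Cd/kg (0), 11098 passed with array weights, 11196 with weights per group, 11035 with the 2 groups alone, 8 with the slide as a block, 7568 on slide 1 and 1 on slide 2. Between doses (27), 94 passed among probes above background on all 9 arrays, 83 with array weights, 56 with cyclic loess, 51 with trend and robust options, 61 with scan session as a random block, 2229 on slide 1, 16 with normexp and quantile, 10 with quantile, 7 with the slide as a block, 2 with no filter, and 0 with the 2 groups alone, weights per group, spike-in scaling, the scan session block or slide 2. In the F test (1), 1754 passed among probes above background on all 9 arrays, 15373 with array weights, 7394 with weights per group, 157 with cyclic loess, 123 with normexp and quantile, 2 with quantile, with scan session as a random block and on slide 2, 12471 on slide 1, 4939 with the slide as a block, and 0 with no filter, spike-in scaling or the scan session block. Where a slide or an arm held 1 array of a group, that array was assumed to vary like the others: the spread came from 2 controls on slide 1 and from 2 of the 16 mg arrays on slide 2, and the groups differ in spread (median SD 0.20 in controls and 0.38 at 16 mg), so these counts do not show a dependence on the slide. The scan session block left control array 3 as the only control that informs the contrasts, so its counts against control do not show a dependence on session. Leaving out each array gave 0 to 9206 probes at 5 mg, 0 to 4657 at 16 mg, 0 to 30 between doses and 0 to 7274 in the F test. Spike-in scaling moved the median of all probes at 5 mg Cd/kg from -0.25 to -0.62, normexp with quantile to -0.01, the probes above background on all 9 arrays to 0.21 and no filter to 0.17; at 16 mg it went from -0.07 to -0.23, -0.01, 0.27 and 0.07 in this order. Apart from the filter and the left-out samples, which change the number of probes or arrays, the cause was not tested. With the replicate number as a block, 1899 probes passed at 5 mg, 0 at 16 mg, 0 between doses and 0 in the F test. Deviations of arrays with the same number correlated at -0.10 to 0.33. Arrays with different numbers were not set beside them, so a pairing of the samples was neither shown nor excluded. A choice of 1 probe per gene and the gene lists were not run. Dim probes are limited by the background: 17234 to 25443 probes per group were above it on all 3 arrays.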

Other observations

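The tests of the spread of levels were chosen after the result was seen. Those of the probe classes were written before theirs, apart from the median without the highest cadmium array, which the written prediction did not hold. Among the 16952 probes above background on all 9 arrays, levels spread over a wider range in cadmium arrays. The range from the 10th to the 90th percentile was 6.55 ± 0.10 on the log2 scale in controls, 7.22 ± 0.41 at 5 mg and 7.26 ± 0.22 at 16 mg Cd/kg (SD, n = 3 each; exact permutation tests, two-sided, p = 0.1 for each dose, the smallest possible). In 5 bins of equal size from the dimmest to the brightest probes, the median log2 fold changes were -0.21, -0.16, 0.14, 0.56 and 0.61 at 5 mg, and -0.31, -0.20, 0.27, 0.54 and 0.57 at 16 mg Cd/kg.

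The SD of the levels widened by 9.33% in probes and by 1.37% in the 8 spike-ins (95% bootstrap interval -1.59 to 6.29). This argues against a response of labelling, hybridisation and scanning as the whole cause, if that response acts alike at all levels. The dimmest spike-in had a mean level of -1.56, the next 1.33 and the brightest 11, while the 2 dimmest bins of probes at 5 mg had medians of -1.43 and -0.42. The spike-ins thus say little about a response that acts on dim probes. The upper bound of 6.29 lies above 4.66, the value at which that response and all other causes would contribute equally, so a part of it may still come from that response and cannot be told apart. Against control array 3, scanned in the same session on the same slide, the brightest minus the dimmest bin was 0.704 for 5 mg array 2 and 0.686 for 16 mg array 1, beside 0.865 and 0.829 against all controls and -0.024, -0.127 and 0.19 for each control against the other 2, which argues against slide and session for these 2 arrays. The other 4 cadmium arrays were scanned in sessions with no control array, so for them session cannot be told apart from group. RNA quality and a response of the embryos to cadmium stay open, as untested.

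Read-named probes lay above contig-named probes in cadmium arrays, by 0.54 on the log2 scale for the mean of both doses. Among probes of like level the difference was 0.329 (mean over 10 bins of level, 95% bootstrap interval 0.302 to 0.356), so most of it remained, which argues against the dependence on level as the main cause, though it may account for part. The interval does not cover the spread between arrays, as the class difference ran from -0.06 to 0.88 over the cadmium arrays. Against a single array as the source, the written prediction was that all 6 cadmium arrays exceed the controls. It failed, as 5 mg array 1 lay at -0.06. The other cadmium arrays lay at 0.42 to 0.88, so the difference did not rest on 1 array. Without the highest cadmium array the median was 0.433, a measure that was not part of that prediction. What the classes differ in, such as the region of the transcript that a probe covers, was not tested here, so a technical or biological source is left open.

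Other groupings of the arrays were fitted as a check on chance. Of the 10 splits of control and 5 mg arrays, 1 called as many as the real 3756 (highest of the others 0), and of the 10 splits of control and 16 mg arrays, 10 called as many as the real 0 (highest of the others 0); 10 splits cannot give a share under 0.05. In the F test, 5 of 100 drawn splits of 280, the real one included, called at least the 1 probe of the real grouping, so chance is not excluded for that count. Splits that mixed controls with cadmium arrays called at most 2 probes. Of the 4 other drawn splits that kept the 3 controls together, 2 called 4079 and 563 probes and 2 called 0. These splits still set controls against cadmium arrays, so their counts do not measure chance. Why 2 of them called more probes than the real grouping was not resolved.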
